A study of Mus musculus with 18 samples.

How the data were processed

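Gene expression was measured by RNA sequencing in 18 libraries of cells labelled as mouse bone marrow-derived dendritic cells. Each of the groups ctrl, OVA, IL12, OVA-IL12, OVAoIL12 and OVApIL12l had 3 libraries. Per the labels' protocols, wild-type cells were kept in medium with 10% fetal bovine serum and transfected with 1 µg of mRNA, RNA was taken with Trizol after 24 h, and libraries were made with a VAHTS kit from RNA with an integrity number above 7. Per the submitters' processing notes, HISAT2 and HTSeq were used with genome build mm10, and their versions and settings are not given in the sources used here. The file headers place the genes on GRCm38.p6. Group and replicate number came from the sample titles. The column names of OVApIL12l lack the final l of its titles, and those columns were matched by the rest of the name and the replicate number. What the ctrl cells received is not given in the sources used here.

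The authors deposited whole-number counts per gene for 55487 genes, which were tested as deposited. A pair of normalized tables was also deposited, named for FPKM and TPM per the file headers. As deposited by the authors, both held CPM, the counts divided by the library total and scaled to 1000000. Their values differed from CPM computed here from the counts by at most 3.6e-12 and 2.3e-09 (tolerance 1e-06). The planned test on TPM was therefore run on log2(CPM + 1). CPM in the text were computed from the counts, with the SD over 3 libraries. Total counts per library ran from 18382497 to 23990475, so that a count of 3, the floor used for genes without a count, was at most 0.163 CPM. Where molecules were not tagged, the floor covers counting error of reads only. Standard errors of log2 fold changes come from the fit and include the estimated spread between libraries. No pair of libraries in a group held the same values within sampling noise, with chi-square per degree of freedom from 4.27 to 275.

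The groups, 11 comparisons, 23 gene lists, the tests and the alternatives were fixed before the data were examined. The test was edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, trimmed mean of M-values factors, filterByExpr by group) on all 18 libraries, which share an estimate of the spread, with no replicate block. It covered 13328 genes, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 fold changes are standard errors of the fit. For gene lists the members that passed were counted over all genes and adjusted over the list alone, and the 20 lists with at least 3 tested members were tested with limma camera (version 3.58.1) with the correlation between genes estimated, adjusted over 220 tests. The lists covered interferon, antigen presentation, maturation, inflammation, RNA sensing, IL-12, cell cycle, stress and metabolic genes, and markers of other cell types. Genes were named by a fixed rule. Il12a and Il12b were named throughout, and a panel of 13 maturation and cytokine genes in comparisons with ctrl. Up to 5 higher and 5 lower genes of largest change were named among those that passed, with an average log2 CPM of at least 1 and no overlap between the groups' libraries. Up to 3 members of each list with the smallest p were named as well. The text names fewer where calls repeat.

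The replicate numbers come from the titles. Whether they pair the libraries was checked by correlating deviations from group means, with a limit of 0.1 for every pair. The numbers paired the libraries in 10 of 11 comparisons, with correlations from 0.112 to 0.867, and not in IL12 against ctrl. A fit with the replicate number as a block was chosen before the data were seen. After the data were seen, a fit to the 12 libraries of replicates 2 and 3 was added (13204 genes), with the rules on largest changes and list members applied to its tests and libraries, since the replicate 1 libraries stood apart. This fit leaves 6 residual degrees of freedom, against 12 over 18 libraries. The biological coefficient of variation was 0.269 over 18 libraries, 0.134 with the block and 0.0882 within replicates 2 and 3.

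Other alternatives were DESeq2 1.42.0, limma on log2(CPM + 1) with a pseudocount of 1, edgeR with RLE factors, no filter on low counts, an average CPM of at least 5, a log2 fold change of at least 1, only the groups compared, camera with a preset correlation of 0.01 and leaving out each library in turn. DESeq2 gave no adjusted p for 18 genes, which were not counted as lost. The steps were tested on simulated data drawn from the mean levels and library totals of these libraries, with 200 of 13328 genes changed between OVA and ctrl. Over 18 libraries edgeR recovered 50% of 68 genes changed 2-fold, 87.3% of 71 changed 4-fold and 88.5% of 61 changed 8-fold, with 9 false calls. With the libraries of replicates 2 and 3 it recovered 74.3%, 89.1% and 93.5%, of 74, 64 and 62 genes, with 11 false calls among 13204 genes. Simulated genes were drawn independently, each with its estimated spread and without a shift shared by the replicate 1 libraries. The shares recovered therefore cannot be carried over to these data. In OVA against ctrl 8 of 30 type I interferon genes passed over 18 libraries, at a median log2 fold change of 5.53. Camera was tried on simulated normal values without correlation between genes, and called the 1 raised list of 10 and 0 others. This does not test it on correlated lists such as those of these data. Genes with close copies, among them Apol9a, Apol9b, Ifit3b, Phf11b, H2-T24, H2-K1 and the Oas family, share reads that counting can split, and their values are uncertain. Strand settings of the counting are not given in the sources used here, so genes overlapping on opposite strands are uncertain too.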

Results

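Cells labelled as bone marrow-derived dendritic cells (BMDCs) were profiled by bulk RNA sequencing 24 h after transfection with 1 µg of mRNA. BMDCs are antigen-presenting cells grown from mouse bone marrow precursors. Marker levels in these libraries are given under other observations, and the makeup of the cultures was not tested. The series concerns a vaccination scheme called time-ordered expression (TOE) and the activation and maturation of these cells. The 18 libraries fell into 6 groups of 3: ctrl, OVA, IL12, OVA-IL12, OVAoIL12 and OVApIL12l. OVA is ovalbumin, a model antigen from chicken egg white, and IL12 is interleukin 12, a cytokine made of the subunits encoded by Il12a and Il12b. The labels do not spell out what the hyphen or the letters o, p and l stand for in the names of the combined groups, nor what the ctrl cells received. The 5 groups other than ctrl are called the mRNA groups. Total counts ran from 18382497 in IL12 replicate 2 to 23990475 in OVA-IL12 replicate 3, and 3 counts corresponded to at most 0.163 CPM (counts scaled to a library total of 1000000) in any library. The labels do not state that replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

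The libraries numbered 1 stood apart from those numbered 2 and 3 in every group. On the first principal component, which held 60.3% of the variance, all 6 replicate 1 libraries lay between -75.0 and -36.2, and replicates 2 and 3 of the 5 mRNA groups lay between 25.5 and 53.7. Replicates 2 and 3 of ctrl lay at -43.2 and -41.9 and were separated from the rest on the second component, with 15.8% of the variance. Of 13328 genes, 8254 differed between replicate 1 and the other libraries in a model that also held the group, 4280 higher and 3974 lower in replicate 1. Each comparison is therefore given over 18 libraries, which was the planned test, and within replicates 2 and 3, a choice made after the data were seen. Replicate 1 has 1 library per group, so its log2 ratios have no replicate check.

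**Figure D1:**
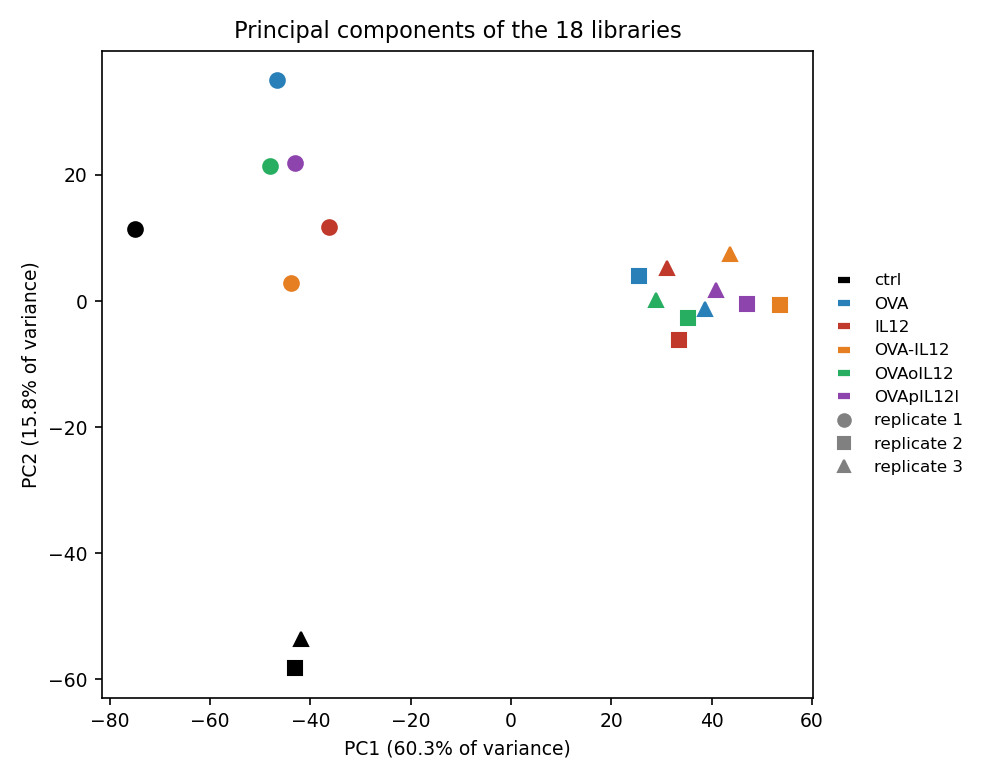
Principal components 1 and 2 of log2 expression in the 18 libraries, each point a library, colour giving the group and shape the replicate number. The replicate 1 libraries of all 6 groups lie between -75.0 and -36.2 on the first component, while replicates 2 and 3 of the 5 mRNA groups lie between 25.5 and 53.7.

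Reads assigned to Il12a and Il12b served as a check of the labels. Il12a (ENSMUSG00000027776, GRCm38.p6 chromosome 3, 68690644 to 68698547, plus strand) had 5.67 ± 2.94 CPM in ctrl and 3987 ± 3248 CPM in IL12 (mean ± SD, n = 3 each). Its mean was 10.9 ± 0.287 CPM in OVA, 1966 ± 1683 in OVA-IL12, 2054 ± 1583 in OVAoIL12 and 1649 ± 1353 in OVApIL12l. Il12b (ENSMUSG00000004296, chromosome 11, 44400063 to 44414033, plus strand) had 3.60 ± 1.30 CPM in ctrl, 7.10 ± 0.346 in OVA and 2843 ± 2313 in IL12. All 12 libraries of the 4 groups with IL12 in their name lay above all 6 ctrl and OVA libraries in both genes. The SDs were nearly as large as the means because replicate 1 carried far fewer of these reads: Il12a in replicate 1 was 0.0683 of the mean of replicates 2 and 3 in IL12, 0.0102 in OVA-IL12, 0.0768 in OVAoIL12 and 0.0389 in OVApIL12l. The counts do not separate reads of the cells' own Il12a and Il12b from reads of a transfected mRNA, and OVA has no mouse gene to be counted at.

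**Figure D2:**
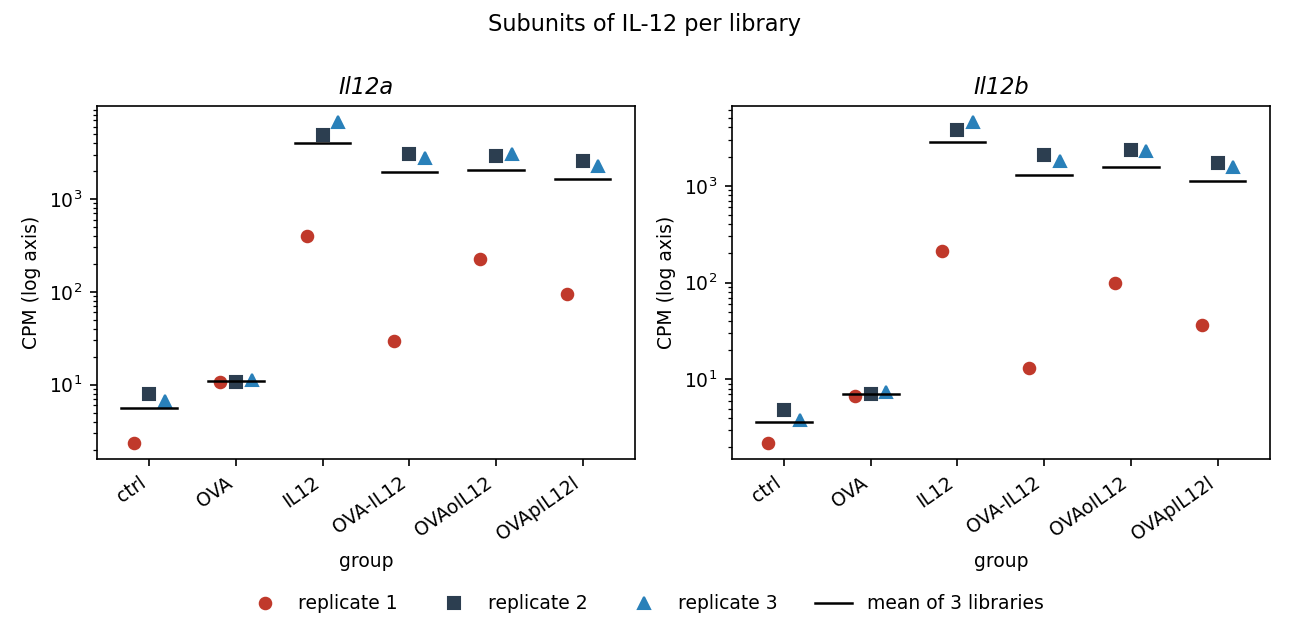
CPM of Il12a and Il12b (log axis) in each library by group, with the replicate number as shape and the mean of the 3 libraries as a line. The 12 libraries of the groups named with IL12 lie above all ctrl and OVA libraries, and in each of these groups replicate 1 is the lowest library.

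OVA against ctrl set cells given the antigen mRNA alone against ctrl. What ctrl received is not given, so effects of transfection as such cannot be told apart from effects of this mRNA. Among the named genes that passed, those induced by interferon changed most. Isg15, which encodes a ubiquitin-like antiviral protein (ENSMUSG00000035692, chromosome 4, 156199455 to 156200796, minus strand), had 499.7 ± 243 CPM in OVA and 10.2 ± 1.06 CPM in ctrl, a log2 fold change of 5.71 ± 1.07 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0455). Oasl2, a member of the 2'-5' oligoadenylate synthetase family, rose by 6.72 ± 1.19 on the log2 scale, Cmpk2, a mitochondrial nucleotide kinase, by 5.79 ± 1.09, Oas3 by 5.15 ± 0.97 and Zbp1, a sensor of Z-form nucleic acid, by 5.15 ± 0.90. The smallest adjusted p belonged to Rtp4, an interferon-induced gene on chromosome 16, at 202 ± 19.2 CPM in OVA and 12.7 ± 3.18 CPM in ctrl (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.55e-04, log2 fold change 4.07 ± 0.36, higher in 3 of 3 libraries). Fos, an immediate early transcription factor, went the other way at -1.44 ± 0.23, followed by Rufy4 at -1.41 ± 0.26, Rhob at -0.93 ± 0.17, the neonatal Fc receptor gene Fcgrt at -0.89 ± 0.15 and Dnajb14 at -0.87 ± 0.15. In each of these named genes the 3 OVA libraries lay on 1 side of all 3 ctrl libraries. The naming rule required this of the genes with the largest changes, so it is no added support for them.

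Over all genes, 29 changed, 18 higher and 11 lower (edgeR quasi-likelihood, 13328 genes tested). Same-numbered libraries deviated together, and with the replicate number as a block the count was 1577, 1010 higher and 567 lower. Within replicates 2 and 3 it was 3877, 2205 higher and 1672 lower, and all 29 genes remained among them. The 18-library count rested on single libraries: it was 893 without ctrl replicate 1, 3 without OVA replicate 1, and 1 without ctrl replicate 2, ctrl replicate 3, OVA replicate 2 or OVA replicate 3.

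The list of type I interferon-stimulated genes had 8 of 30 members higher, 30 of 30 when adjusted over the list alone, 30 of 30 with the replicate block and 30 of 30 within replicates 2 and 3, with a median log2 fold change of 5.53 over 18 libraries. The median log2 ratio of CPM + 1 was 3.12 in replicate 1 and 5.10 in replicates 2 and 3, with 30 of 30 members higher in both. Of 24 tested genes known as targets of interferon-gamma, 0 passed over all genes with edgeR's quasi-likelihood test, 21 when adjusted over the list alone, 21 with the block and 24 within replicates 2 and 3. Their median log2 fold change within replicates 2 and 3 was 4.72, or 4.07 with the 2 members that had no ctrl count, Cxcl11 and Tgtp1, set to their lower bounds. MHC class I presentation genes gave 0 of 19 over all genes, 19 adjusted over the list alone, 19 with the block and 19 within replicates 2 and 3. Among the genes of the RNA sensing list 1 of 18 passed over all genes, 9 higher and 1 lower adjusted over the list alone, and 13 higher and 2 lower within replicates 2 and 3. The chemokine gene Cxcl10 went from 11.1 ± 7.37 to 867 ± 610.0 CPM, a log2 fold change of 6.39 ± 1.65 that did not pass over 18 libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.103) and was 7.57 ± 0.19 within replicates 2 and 3, where it passed, and 3.25 in replicate 1. With the block its log2 fold change was 4.81 and passed.

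Interferon genes were without a count in ctrl: Ifnb1 had 0 counts in all 3 ctrl libraries and 5.94 ± 4.93 CPM in OVA, at least 39.2-fold higher when set against 3 counts in 1 ctrl library. Ifna4 was at least 12.6-fold and the interleukin 21 receptor gene Il21r at least 18.2-fold higher on the same floor. Means in replicates 2 and 3 were 8.63, 2.84 and 3.95 CPM for Ifnb1, Ifna4 and Il21r, and Ifna4 in OVA replicate 1 lay under the level of 3 counts. Il12a and Il12b, with 1.01 ± 1.39 and 1.05 ± 1.52 over 18 libraries, rose by 0.70 ± 0.20 and 0.88 ± 0.19 within replicates 2 and 3. Neither Ifnb1 nor Ifna4 nor Il21r passed over 18 libraries, and all 3 passed with the block and within replicates 2 and 3. Of the maturation genes, Cd86, a costimulatory ligand of T cells, had 51.0 ± 31.8 CPM against 17.3 ± 5.60 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.439 over 18 libraries), a log2 fold change of 1.87 ± 0.17 within replicates 2 and 3 and 0.47 in replicate 1. Cd80 was flat at -0.04 ± 0.50 over 18 libraries, Cd83 was at 0.890 ± 0.400 against 2.17 ± 1.38 CPM, Cd40 was at 0.211 ± 0.189 CPM and Ccr7, the receptor that guides mature dendritic cells to lymph nodes, had 0 counts in both groups. Cd83 fell by 1.30 on the log2 scale within replicates 2 and 3. Il6 was 13.7 ± 5.68 against 1.94 ± 1.05 CPM, with 3.74 ± 0.24 on the log2 scale within replicates 2 and 3 and 1.34 in replicate 1, and H2-K1, a classical MHC class I gene, 3047 ± 1659.8 against 691 ± 37.9 CPM, with 2.66 ± 0.17 and 0.76. With the block Cd86, Cd83, Il6 and H2-K1 also passed, at 1.36, -1.13, 2.73 and 1.79. Tnf was 0.91 ± 0.60 over 18 libraries and 1.18 ± 0.20 within replicates 2 and 3, Il1b 0.10 ± 0.40 and 0.39 ± 0.33, and H2-Ab1, of MHC class II, 1.10 ± 0.43 and 1.49 ± 0.37; Tnf and H2-Ab1 passed within replicates 2 and 3 and none of these genes passed over 18 libraries.

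Within replicates 2 and 3, 3877 of 13204 genes passed, 2205 higher and 1672 lower, which is the background for counts of list members there. In that fit 16 of 20 cholesterol biosynthesis genes fell, with a median of -0.52. Of the glycolysis and hypoxia genes 14 of 20 rose, with a median of 0.51. NF-kB-driven inflammatory genes had 12 of 18 higher, the unfolded protein response 13 of 20 higher and 3 lower, maturation and costimulation 11 of 19 higher and 1 lower, MHC class II presentation 6 of 14 higher and the cell cycle 3 of 25 higher. The IL-12 family and its receptors had 9 of 14 higher and 2 lower, the endocytic and scavenger receptors 5 of 14 higher and 6 lower, and the apoptosis and p53 targets 8 of 16 higher and 5 lower. Over 18 libraries 0 members of these 10 lists passed edgeR's quasi-likelihood test over all genes. Adjusted over the list alone, 3 NF-kB-driven genes and 5 of the unfolded protein response rose, 1 apoptosis gene rose and 2 fell, and 0 members of the other lists passed. With the block and adjusted over the list alone, 16 of 25 cell cycle genes, 13 of 20 of the unfolded protein response, 9 of 20 glycolysis genes, 9 of 18 NF-kB-driven genes, 6 of 18 maturation genes and 2 of 14 class II genes were higher. In the same fit 7 of 20 cholesterol genes, 2 of the unfolded protein response and 1 maturation gene were lower. The endocytic and scavenger receptors had 4 higher and 6 lower there, the IL-12 family 6 higher and 2 lower, and the apoptosis and p53 targets 5 higher and 4 lower. The cell cycle list had 25 of 25 members higher in replicate 1 and 25 of 25 in replicates 2 and 3, with median log2 ratios of CPM + 1 of 0.48 and 0.66. The glycolysis list had 7 of 20 and 19 of 20 higher, with medians of -0.12 and 0.39. Of 13 mitochondrially encoded transcripts, 10 fell within replicates 2 and 3, and 5 fell when adjusted over the list alone. The mitochondrial share of counts was 3.59 ± 1.17% in ctrl and 2.01 ± 0.204% in OVA. In replicate 1 alone it was 2.24% and 2.23%.

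Markers of other cell types were counted within replicates 2 and 3 too, where the macrophage list had 1 of 12 higher and 4 lower, the neutrophil list 1 of 7 higher and 2 lower, the plasmacytoid list 3 of 6 higher, the conventional dendritic cell 1 list 1 of 6 higher and 2 lower, and the list of conventional dendritic cell 2 and monocyte-derived cells 2 of 8 higher and 2 lower. Of the basophil and mast cell markers, 1 of 2 tested rose, the histidine decarboxylase gene Hdc, and of the erythroid markers 1 of 2 fell, the erythropoietin receptor gene Epor. With 3877 of 13204 genes passing in this fit, counts this small do not show that these lists changed more than other genes. Over 18 libraries 0 members of these 7 lists passed over all genes with edgeR's quasi-likelihood test. Adjusted over the list alone, 1 basophil, 1 conventional dendritic cell 1 and 1 conventional dendritic cell 2 marker rose, and 1 neutrophil and 1 marker of each conventional dendritic cell list fell. The 19 T, B and NK cell markers were under 1 CPM in every library. Camera, a competitive test of gene lists, called the type I interferon list with a preset correlation of 0.01 (adjusted p = 7.35e-28). With the correlation estimated, at 0.97 for this list, camera gave an adjusted p of 0.818. The preset is far below that estimate, so the call with it is not evidence on the list. Over all 220 tests of 20 lists in 11 comparisons, 73 were called with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.818. With estimated correlations the lowest adjusted p was 0.284 with the replicate block and 0.274 within replicates 2 and 3.

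**Figure D3:**
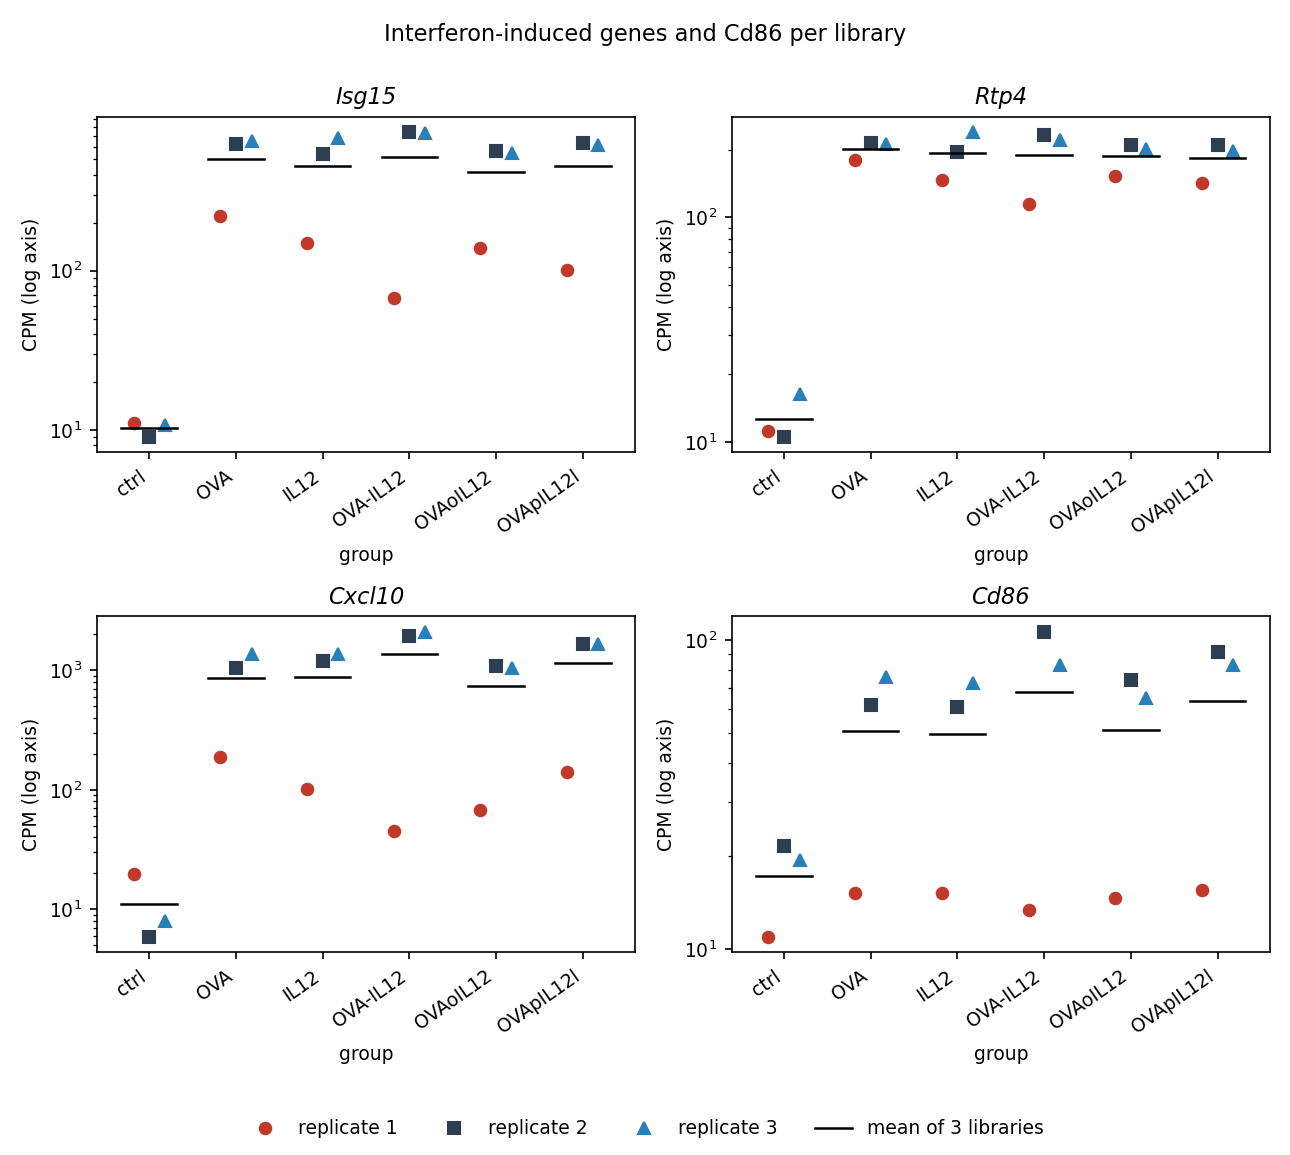
CPM of Isg15, Rtp4, Cxcl10 and Cd86 (log axis) in each library by group, with the replicate number as shape and the mean of the 3 libraries as a line. Isg15 and Rtp4 lie above ctrl in every library of the mRNA groups, with Rtp4 at 202 ± 19.2 CPM in OVA (mean ± SD), while Cxcl10 and Cd86 are lower in replicate 1 than in replicates 2 and 3 of every mRNA group.

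IL12 against ctrl set cells given the cytokine mRNA without the antigen against ctrl. Here too, effects of transfection or of any mRNA cannot be told apart from effects of IL12. Among the named genes that passed, interferon-stimulated genes again changed most: Oasl2 had 605 ± 349 CPM in IL12 and 6.27 ± 2.14 in ctrl, a log2 fold change of 6.72 ± 1.19 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0464), with Cmpk2 at 5.89 ± 1.10, Isg15 at 5.61 ± 1.07, Oas3 at 5.14 ± 0.97 and Zbp1 at 5.09 ± 0.89. Rtp4 was 4.04 ± 0.36 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.67e-04), Oas2 2.93 ± 0.46 and Eif2ak2, the kinase PKR that is activated by double-stranded RNA, 1.94 ± 0.38. Fos at -1.20 ± 0.23, Bvht at -0.89 ± 0.17, Fcgrt at -0.77 ± 0.15, Clec1b at -0.74 ± 0.14 and Iffo1 at -0.72 ± 0.13 were lower. In all of these genes the 3 IL12 libraries lay on 1 side of all 3 ctrl libraries. For the genes named for the largest changes this follows from the naming rule and is no added support.

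Il12a was 9.60 ± 1.94 and Il12b 9.76 ± 2.11 on the log2 scale, and did not pass over 18 libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0502 and 0.0545). Within replicates 2 and 3 they were 9.78 ± 0.22 and 10.07 ± 0.19 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.32e-11 and 6.15e-12), and over the 14 alternative fits the adjusted p ran from 1.32e-11 to 0.297 for Il12a and from 6.15e-12 to 0.332 for Il12b. Ifnb1 was at least 37.5-fold higher than the floor of 3 counts in 1 ctrl library, at 5.69 ± 4.59 CPM, and Ifna4 at least 11.9-fold. Their means in replicates 2 and 3 were 8.29 and 2.65 CPM, and Ifna4 in IL12 replicate 1 lay under the level of 3 counts. Within replicates 2 and 3 Cxcl10 rose by 7.68 ± 0.19, Il6 by 3.80 ± 0.24, H2-K1 by 2.36 ± 0.16, Cd86 by 1.85 ± 0.17 and Tnf by 1.31 ± 0.20, against 2.37, 0.49, 0.56, 0.48 and -0.27 in replicate 1. None of these 5 passed over 18 libraries. Cd80 was 0.03 ± 0.10 and Il1b 0.29 ± 0.33 within replicates 2 and 3, and neither passed. Cd83 was -1.25 ± 0.25, which passed, and H2-Ab1 0.90 ± 0.38, which did not. Cd40 was at 0.169 ± 0.101 CPM and Ccr7 had 0 counts. Genes that fell there included Ifi27 at -2.73 ± 0.13, Gpr34 at -2.06 ± 0.34 and Gprc5c at -2.03 ± 0.14.

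The type I interferon list had 8 of 30 members higher over all genes and 30 of 30 both adjusted over the list alone and within replicates 2 and 3, with a median log2 fold change of 5.46. Its median log2 ratio of CPM + 1 was 2.89 in replicate 1 and 5.14 in replicates 2 and 3. Interferon-gamma-induced genes had 0 of 24 over all genes with edgeR's quasi-likelihood test, 20 adjusted over the list alone and 24 within replicates 2 and 3. MHC class I genes gave 0, 18 and 19 of 19 in the same order. RNA sensing gave 2, 9 and 13 of 18 higher, and 1 lower adjusted over the list alone and 2 lower within replicates 2 and 3. Adjusted over the list alone 0 mitochondrial and 0 cholesterol genes passed. Of the mitochondrial transcripts 11 of 13 fell within replicates 2 and 3, and of the cholesterol genes 8 of 20. NF-kB-driven genes had 11 of 18 higher and maturation genes 11 of 19 higher and 1 lower there, with medians of 0.86 and 0.48 as log2 ratios of CPM + 1 against 0.22 and 0.07 in replicate 1, and neither list had a member past edgeR's quasi-likelihood test over 18 libraries, 0 adjusted over the list alone. The mitochondrial share was 2.45 ± 0.465% in IL12 against 3.59 ± 1.17% in ctrl. It went the other way in replicate 1, at 2.96% against 2.24%, while replicates 2 and 3 had a mean of 2.20% against 4.27%. Over all genes 45 changed, 30 higher and 15 lower, and within replicates 2 and 3 the count was 3606, with all 45 remaining. It was 408 without ctrl replicate 1, 2 without IL12 replicate 1, and 1 without ctrl replicate 2, ctrl replicate 3, IL12 replicate 2 or IL12 replicate 3.

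OVA-IL12 against ctrl had 21 of 30 type I interferon genes and 5 of 18 NF-kB-driven genes higher. Of the latter, Ccl2, a chemokine that recruits monocytes, went from 0.734 ± 0.198 to 26.1 ± 21.7 CPM, a log2 fold change of 5.30 ± 1.32 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0428), Il6 from 1.94 ± 1.05 to 24.6 ± 18.5 CPM (3.81 ± 0.94) and Il1a from 255 ± 23.7 to 892 ± 474 CPM (1.95 ± 0.47). Nos2, the inducible nitric oxide synthase, rose by 3.70 ± 0.72, Cxcl10 by 7.10 ± 1.70, and the guanylate-binding protein genes Gbp3 and Gbp6 by 6.42 ± 1.34 and 3.25 ± 0.67. The largest increases beside Il12b (8.64 ± 2.02) and Il12a (8.59 ± 1.87) were Apol9b at 8.54 ± 2.17, Phf11b at 7.99 ± 1.92 and Apol9a at 7.93 ± 2.002, members of families with near-identical copies whose reads the counting could split, so their single values are uncertain. Rufy4 at -1.61 ± 0.26, Prss30 at -1.56 ± 0.32, Fos at -1.47 ± 0.23, Cbr2 at -1.37 ± 0.28 and Vstm2a at -1.30 ± 0.30 were lower.

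By list, 21 of 30 type I interferon genes were higher over all genes, and 30 of 30 adjusted over the list alone, with the block and within replicates 2 and 3. Interferon-gamma-induced genes had 10 of 24 higher, 23 adjusted over the list alone and 24 with the block. MHC class I presentation had 3 of 19 higher, among them the peptide transporter gene Tap1 at 3.54 ± 0.82 and the transactivator gene Nlrc5 at 3.41 ± 0.88, and 19 of 19 adjusted over the list alone. NF-kB-driven genes had 5 of 18 higher, 14 adjusted over the list alone, 13 with the block and 18 within replicates 2 and 3. RNA sensing had 7 of 18 higher, among them Dhx58 at 4.20 ± 0.85, and 10 higher and 1 lower adjusted over the list alone. Of 20 glycolysis and hypoxia genes 2 rose, the hexokinase gene Hk2 by 0.95 ± 0.18 and Hif1a by 0.56 ± 0.14, with 3 adjusted over the list alone, 15 under the block and 18 within replicates 2 and 3. Of the cholesterol genes 1 of 20 fell, Insig1 at -0.76 ± 0.20, the same count adjusted over the list alone, with 11 lower under the block and 17 within replicates 2 and 3. In replicate 1 the median log2 ratio of CPM + 1 was 2.19 for the type I interferon list, 0.06 for the NF-kB list and 0.03 for the cholesterol list, against 5.34, 1.62 and -0.95 in replicates 2 and 3.

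Cd86 was 67.8 ± 48.5 against 17.3 ± 5.60 CPM, 2.38 ± 0.17 on the log2 scale within replicates 2 and 3, where it passed, and 0.29 in replicate 1. With the block it passed at 1.68, as did H2-K1 at 1.85, H2-Ab1 at 1.41, Tnf at 1.11 and Cd83 at -1.34, while none of the 5 passed over 18 libraries. Maturation genes as a list had 0 of 18 over all genes with edgeR's quasi-likelihood test and 0 adjusted over the list alone, 12 higher and 1 lower with the block, and 15 of 19 higher and 1 lower within replicates 2 and 3. Their median log2 ratio of CPM + 1 was -0.04 in replicate 1, with 8 of 18 higher, and 0.81 in replicates 2 and 3, with 15 of 18. Itgax, which encodes CD11c, fell by 1.11 ± 0.24 and Irf8, a transcription factor of conventional dendritic cells, by 0.73 ± 0.17 on the log2 scale. The neutrophil collagenase gene Mmp8 was 16.9 ± 5.24 CPM in OVA-IL12 and 59.98 ± 34.4 in ctrl and also fell. In replicate 1 Itgax was 0.01 and Mmp8 0.10 apart from ctrl. Cd80 was 0.15 ± 0.09 and Il1b 1.04 ± 0.33 within replicates 2 and 3, of which Il1b passed. Isg15 rose by 5.81 ± 1.08 over 18 libraries, Cd40 was at 0.351 ± 0.311 CPM and Ccr7 at 0.0152. Macrophage markers had 0 of 12 over all genes with edgeR's quasi-likelihood test and 0 adjusted over the list alone, and 2 higher and 4 lower within replicates 2 and 3. Ifnb1 had 11.45 ± 9.96 CPM, at least 75.5-fold above the floor of 3 counts in 1 ctrl library. That mean came from replicates 2 and 3, at 17.1 CPM, while replicate 1 lay under the level of 3 counts. Of the mitochondrial transcripts 7 of 13 fell when adjusted over the list alone, and the mitochondrial share was 2.30 ± 0.815% in OVA-IL12. In replicate 1 it was higher than in ctrl, 3.24% against 2.24%, and in replicates 2 and 3 lower, 1.84% against 4.27%.

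In all, 457 genes changed, 282 higher and 175 lower (edgeR quasi-likelihood, Benjamini-Hochberg). On log2(CPM + 1) with limma the split was 183 higher and 212 lower. With the replicate block 3111 genes changed, and within replicates 2 and 3 4997, with 455 of the 457 remaining. The count was 839 without ctrl replicate 1, 1321 without OVA-IL12 replicate 1, 11 without ctrl replicate 3, and 1 without ctrl replicate 2, OVA-IL12 replicate 2 or OVA-IL12 replicate 3.

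OVAoIL12 against ctrl changed 5 genes over 18 libraries. Rtp4 rose from 12.7 ± 3.18 to 189 ± 30.8 CPM, a log2 fold change of 3.99 ± 0.35 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.95e-04), and Oas2 from 45.8 ± 15.6 to 327 ± 101 CPM (2.93 ± 0.46). H2-T24, a non-classical MHC class I gene with close relatives nearby, was at 4.44 ± 0.63 and Fam114a1 at 0.58 ± 0.08, while the long non-coding RNA gene Bvht was lower at -1.25 ± 0.17. In each of the 5 the 3 libraries of OVAoIL12 lay on 1 side of the 3 ctrl libraries. Isg15 at 5.46 ± 1.06 and Il12a at 8.61 ± 1.87 lay outside the threshold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0623 and 0.0737).

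With the replicate block 1373 genes changed, 920 higher and 453 lower, and within replicates 2 and 3 3560, 2060 higher and 1500 lower, including all 5. Isg15 was 5.94 ± 0.14 within replicates 2 and 3 and 3.67 in replicate 1, Il12a 8.79 ± 0.21 and 6.58, Cxcl10 7.39 ± 0.19 and 1.78, H2-K1 2.47 ± 0.17 and 0.71, Cd86 1.89 ± 0.17 and 0.41, and Il6 3.54 ± 0.24 and -0.10. All 6 passed within replicates 2 and 3 and with the block. Cd83, at -1.49 ± 0.25 within replicates 2 and 3, and Ifnb1, at least 27.7-fold above the floor of 3 counts in 1 ctrl library, passed in both fits too. The mean of Ifnb1 was 4.21 CPM over the 3 libraries and 6.11 CPM in replicates 2 and 3. Tnf, at 1.08 ± 0.20, passed within replicates 2 and 3 alone, and Cd80, at 0.04 ± 0.10, Il1b, at 0.06 ± 0.33, and H2-Ab1, at 0.89 ± 0.38, did not pass there. Cd40 was at 0.153 ± 0.132 CPM and Ccr7 had 0 counts. The type I interferon list had 2 of 30 over all genes and 30 of 30 adjusted over the list alone, with the block and within replicates 2 and 3. Interferon-gamma-induced genes had 0 of 24 over all genes with edgeR's quasi-likelihood test, 19 adjusted over the list alone and 20 with the block, MHC class I presentation 0, 18 and 19 of 19, and RNA sensing 0, 9 and 10 of 18. Within replicates 2 and 3 NF-kB-driven genes had 10 of 18 higher, maturation genes 10 of 19 higher and 1 lower, cholesterol genes 10 of 20 lower and mitochondrial transcripts 11 of 13 lower. These 4 lists had 0 members adjusted over the list alone. The mitochondrial share was 2.37 ± 0.214%, with 2.61% against 2.24% of ctrl in replicate 1 and 2.25% against 4.27% in replicates 2 and 3, opposite directions. The median log2 ratio of CPM + 1 of the type I interferon list was 2.48 in replicate 1 and 5.04 in replicates 2 and 3. The 18-library count was 404 without ctrl replicate 1, 135 without OVAoIL12 replicate 1, 2 without ctrl replicate 3, and 1 without ctrl replicate 2, OVAoIL12 replicate 2 or OVAoIL12 replicate 3.

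OVApIL12l against ctrl changed 1053 genes, 506 higher and 547 lower. The largest increases were Il12b and Il12a, by 8.39 ± 2.002 and 8.31 ± 1.85, followed by interferon-induced genes: Ifi44 was at 8.27 ± 2.40 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0497), Apol9b at 8.26 ± 2.15 and Ifit3b at 8.19 ± 2.24, with the caution on near-identical copies applying to Apol9b and Ifit3b. Acaa1b, a peroxisomal thiolase gene, at -2.24 ± 0.64, Gprc5c at -2.13 ± 0.44, Prss30 at -1.69 ± 0.33, Mmp8 at -1.68 ± 0.43 and Rufy4 at -1.62 ± 0.26 were lower.

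Of the type I interferon list 28 of 30 were higher over all genes and 30 of 30 adjusted over the list alone, and of the interferon-gamma list 15 of 24 and 22. Gbp7 rose by 4.03 ± 0.90 and Gbp3 by 6.32 ± 1.33. NF-kB-driven genes had 4 of 18 higher, among them Ccl2 at 4.87 ± 1.30, Il6 at 3.42 ± 0.93 and Il1a at 1.67 ± 0.47, with 7 adjusted over the list alone and 9 with the block. RNA sensing had 7 of 18 higher and 1 lower, with Eif2ak2 at 2.04 ± 0.38 and Irf3 at -0.49 ± 0.09, and 9 higher and 2 lower adjusted over the list alone. MHC class I presentation had 4 of 19 higher, 18 adjusted over the list alone, and the class II list 0 higher and 1 lower, the peptide-loading gene H2-DMa at -0.65 ± 0.19. The class II list had 0 members adjusted over the list alone with edgeR's quasi-likelihood test, 2 higher and 2 lower with the block, and 4 higher and 3 lower within replicates 2 and 3, or 7 higher and 3 lower there adjusted over the list alone. Cholesterol genes had 1 of 20 lower over all genes, 8 with the block and 17 within replicates 2 and 3, and maturation genes 0 with edgeR's quasi-likelihood test, 9 of 18 higher and 1 lower with the block and 14 of 19 higher and 1 lower within replicates 2 and 3. In replicate 1 values were higher for 10 of 20 cholesterol and 8 of 18 maturation genes, with a median log2 ratio of CPM + 1 of -0.03 for the maturation list, against 0 of 20 and 15 of 18 in replicates 2 and 3. Of the unfolded protein response 2 of 20 rose, the endoplasmic reticulum chaperone genes Hsp90b1 at 0.65 ± 0.15 and Pdia4 at 0.81 ± 0.19, and 4 adjusted over the list alone. The death-receptor caspase gene Casp8 was higher at 0.75 ± 0.19, and Zmat3 and Phlda3, targets of p53, were lower at -0.56 ± 0.12 and -0.61 ± 0.17. Itgax at -1.02 ± 0.24, Irf8 at -0.86 ± 0.17 and Epor at -0.95 ± 0.24 were lower and the Toll-like receptor gene Tlr11 higher at 4.62 ± 1.26. Tlr11 had 0.151 ± 0.152 CPM in ctrl, near the level of 3 counts, so the size of its change is uncertain. Of 25 cell cycle genes 0 passed over all genes with edgeR's quasi-likelihood test or adjusted over the list alone, 13 rose with the block and 4 within replicates 2 and 3. Of 13 mitochondrial transcripts 0 passed over all genes or over the list alone, 8 fell with the block and 11 within replicates 2 and 3. The mitochondrial share was 2.47 ± 0.763%. In replicate 1 it was higher, 3.35% against 2.24% of ctrl, with 10 of 13 transcripts higher, and in replicates 2 and 3 lower, 2.03% against 4.27%.

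Cd86 was 63.4 ± 41.6 against 17.3 ± 5.60 CPM and did not pass over 18 libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.195). It was 2.23 ± 0.17 within replicates 2 and 3 and 0.50 in replicate 1, and passed with the block at 1.62. H2-K1 passed with the block at 1.48, Cd83 at -1.30 and Tnf at 0.96, while Cd80 at 0.06 ± 0.49 and Il1b at 0.19 ± 0.40 passed in none of the 3 fits. H2-Ab1, at 1.29 ± 0.37, passed within replicates 2 and 3 alone. Isg15 rose by 5.59 ± 1.07 and Cxcl10 by 6.81 ± 1.68 over 18 libraries, Cd40 was at 0.251 ± 0.222 CPM and Ccr7 had 0 counts. Ifnb1 had 8.45 ± 7.21 CPM, at least 55.7-fold above the floor of 3 counts in 1 ctrl library, with a mean of 12.5 CPM in replicates 2 and 3. In replicate 1 the median log2 ratio of CPM + 1 of the type I interferon list was 2.53, against 5.27 in replicates 2 and 3. On log2(CPM + 1) with limma the split of calls was 359 higher and 632 lower. With the replicate block 3889 genes changed and within replicates 2 and 3 4705, with 1027 of the 1053 remaining. The 18-library count of 1053 was 66 without ctrl replicate 2, 512 without ctrl replicate 3, 525 without OVApIL12l replicate 2 and 143 without OVApIL12l replicate 3.

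**Figure D4:**
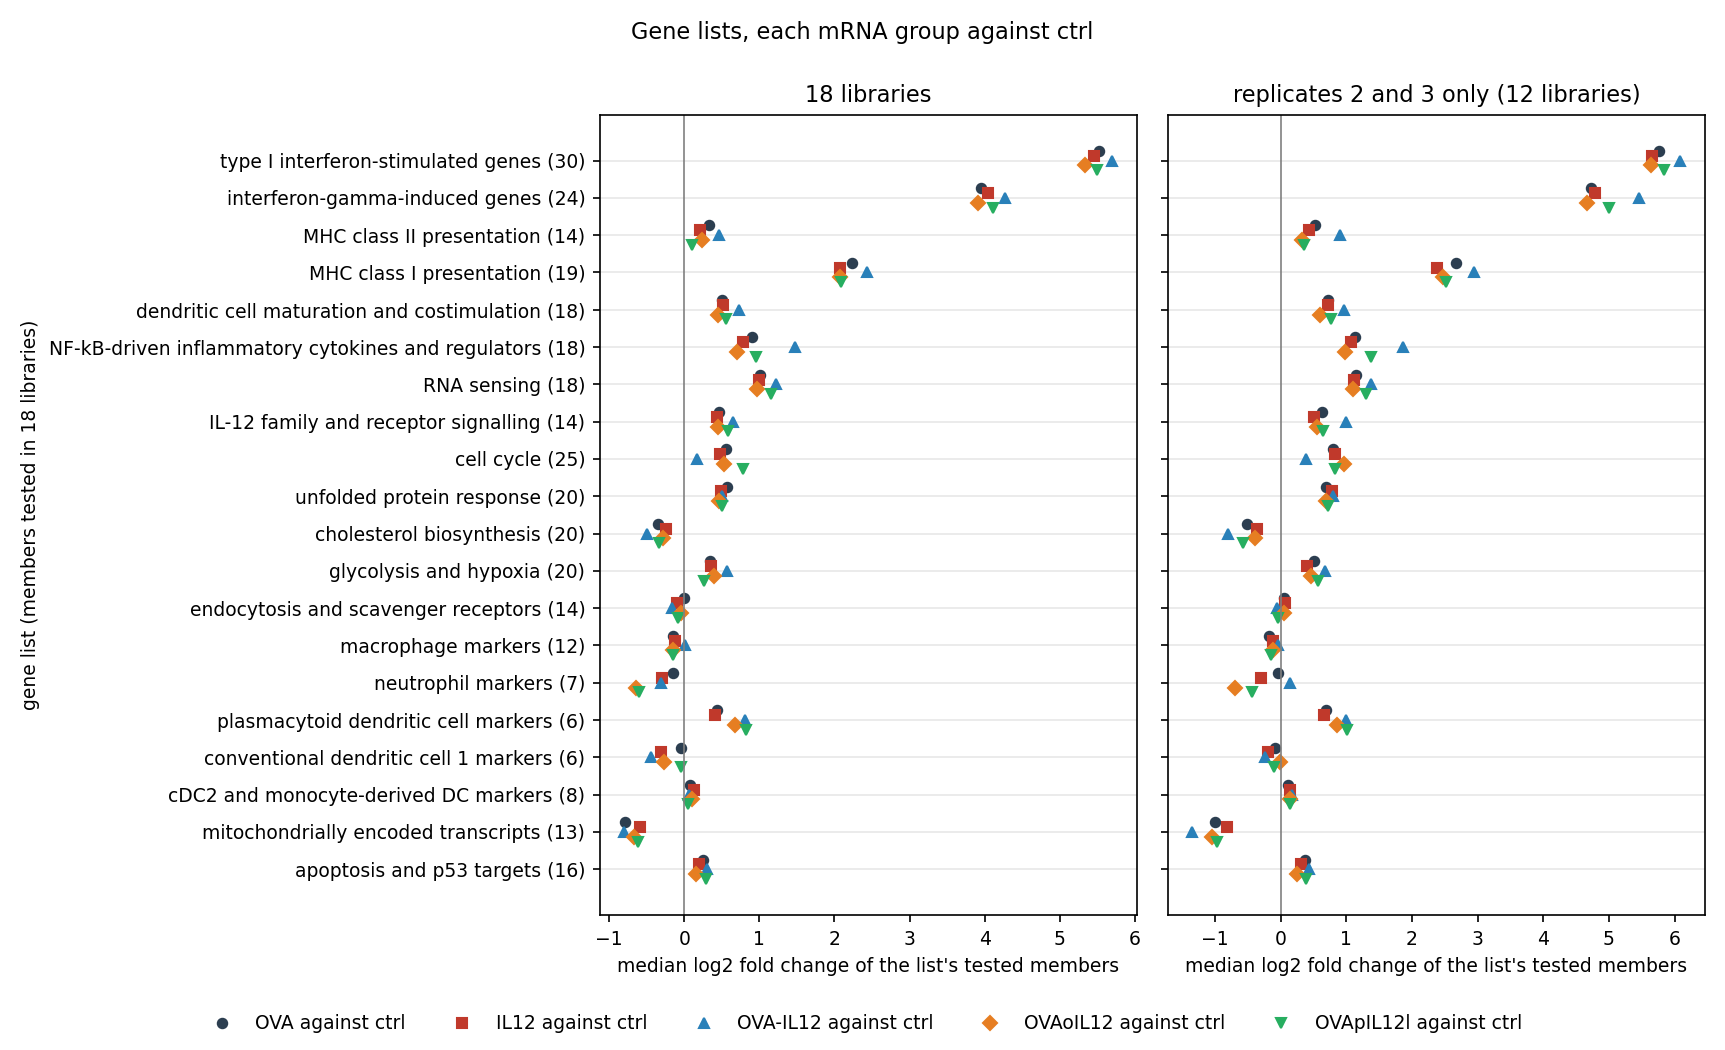
Median log2 fold change of each gene list's tested members (horizontal axis) in the 5 comparisons with ctrl, over 18 libraries (left) and within replicates 2 and 3 (right), with the number of members tested in 18 libraries in parentheses. The type I interferon list lies highest in both panels, at 5.33 to 5.70 over 18 libraries, and the mitochondrial and cholesterol lists lie below 0 in every comparison.

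Further lists were compared across IL12, OVA, OVA-IL12, OVAoIL12 and OVApIL12l against ctrl, in that order. Within replicates 2 and 3, 3606, 3877, 4997, 3560 and 4705 of 13204 genes passed in these comparisons. A list count in that fit near the share over all genes, here or above, does not set the list apart. Of 25 cell cycle genes, 0, 16, 0, 15 and 20 were higher with the block adjusted over the list alone, 3, 3, 2, 5 and 4 within replicates 2 and 3, and 0 in each over 18 libraries with edgeR's quasi-likelihood test. In replicate 1 13, 25, 10, 12 and 23 of the 25 had higher values than in ctrl, and in replicates 2 and 3 25, 25, 19, 25 and 25. Of 20 glycolysis and hypoxia genes, 6, 9, 18, 13 and 3 were higher with the block adjusted over the list alone and 12, 14, 18, 12 and 14 within replicates 2 and 3. Higher values were found for 17, 7, 20, 19 and 4 of the 20 in replicate 1 and for 16, 19, 20, 17 and 19 in replicates 2 and 3. The unfolded protein response had 13, 13, 15, 13 and 15 of 20 higher and 1, 3, 3, 1 and 1 lower within replicates 2 and 3, and 13, 16, 8, 15 and 10 with higher values in replicate 1. Class II presentation had 2, 2, 4, 2 and 2 of 14 higher and 1, 0, 0, 0 and 2 lower with the block, and 2, 6, 8, 2 and 4 higher and 1, 0, 0, 0 and 3 lower within replicates 2 and 3, by edgeR's quasi-likelihood test. Values in replicate 1 were higher than in ctrl for 5, 6, 4, 11 and 3 of the 14 class II genes, 11, 14, 9, 10 and 11 of 18 NF-kB-driven genes, 11, 8, 8, 11 and 8 of 18 maturation genes, 9, 3, 11, 4 and 10 of 20 cholesterol genes and 7, 4, 7, 8 and 10 of 13 mitochondrial transcripts. In replicates 2 and 3 they were higher for 9 class II genes in each comparison, 16, 16, 18, 15 and 17 NF-kB-driven genes and 14, 15, 15, 14 and 15 maturation genes, and for 0 cholesterol genes and 0 mitochondrial transcripts.

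In the 5 comparisons with ctrl the median log2 fold change of the type I interferon list was 5.53 for OVA, 5.46 for IL12, 5.70 for OVA-IL12, 5.33 for OVAoIL12 and 5.503 for OVApIL12l. These share the 3 ctrl libraries and are not independent, and the different numbers of genes changed do not show that the responses differed. The direct comparisons between OVA, OVA-IL12, OVAoIL12 and OVApIL12l test that for these groups. IL12 was compared with ctrl alone, so whether its response differed was not tested.

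OVA-IL12 against OVA set a combined group against the antigen mRNA alone. The protocol gives 1 µg of mRNA for every group. If the combined groups shared that amount, less OVA mRNA cannot be told apart from an effect of IL12 in any comparison with OVA. Within replicates 2 and 3 the IL-12 subunits themselves were the 2 genes that passed over all genes. Il12a had a mean of 2934 CPM against 11.0 there, a log2 fold change of 8.11 ± 0.21 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.13e-10), and Il12b was 8.11 ± 0.17 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.95e-11). In replicate 1 Il12a differed by 1.48. Over 18 libraries Il12a was 7.58 ± 1.79 and Il12b 7.59 ± 1.93, neither passing (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.976), and over the 14 alternative fits their adjusted p ran from 3.13e-10 to 1.00 and from 5.95e-11 to 1.00. No gene passed edgeR's quasi-likelihood test over 18 libraries, with 238 at an unadjusted p under 0.05. The count was 0 with the replicate block and with limma, and DESeq2 called 2, Il12a and Il12b. Over 18 libraries 2 of 14 IL-12 family genes were higher adjusted over the list alone, and 0 members of the other lists passed with edgeR's quasi-likelihood test.

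Interferon-gamma, NF-kB and type I interferon genes were higher in OVA-IL12 than in OVA within replicates 2 and 3 when adjusted over the list alone, and most had lower values in OVA-IL12 in replicate 1, which has 1 library per group and no test. In the fit of replicates 2 and 3, 22 of 24 interferon-gamma-induced genes, 15 of 18 NF-kB-driven genes, 15 of 30 type I interferon genes, 7 of 18 RNA sensing genes and 6 of 19 maturation genes were higher, and 3 of 20 cholesterol genes were lower. Any other list had at most 4 members higher and 2 lower. The median log2 ratio of CPM + 1 was 0.52 for the interferon-gamma list, 0.63 for the NF-kB list and 0.28 for the type I interferon list. In replicate 1 these medians were -0.54, -0.32 and -0.72, with 21 of 24, 13 of 18 and 27 of 30 members lower in OVA-IL12. The maturation list had a median of -0.02 in replicate 1 against 0.36, and the RNA sensing list 0.04 against 0.15. Lists with the same direction in both included the cell cycle, lower in 22 of 25 members in replicate 1 and 25 of 25 in replicates 2 and 3 (medians -0.60 and -0.44), and glycolysis and hypoxia, higher in 20 of 20 and 19 of 20 (0.37 and 0.17). Neither had a member past the threshold in the 3 fits, 0 adjusted over the list alone with edgeR's quasi-likelihood test. With the block, 2 interferon-gamma genes and 1 NF-kB gene were higher adjusted over the list alone, and 0 type I interferon genes passed with edgeR's quasi-likelihood test. The IL-12 family had 3 higher and 1 lower there, the endocytic receptors 2 higher, the plasmacytoid list 1 higher and the conventional dendritic cell 1 list 1 lower.

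In OVAoIL12 against OVA, Il12a was 8.08 ± 0.21 and Il12b 8.32 ± 0.17 within replicates 2 and 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.23e-10 and 4.75e-11), the 2 genes called there. Replicate 1 gave 4.42 and 3.86. The means within replicates 2 and 3 were 2967 and 2321 CPM, against 11.0 and 7.25 CPM in OVA. Over 18 libraries they were 7.60 ± 1.79 and 7.84 ± 1.95 and did not pass, and over the 14 alternative fits the adjusted p ran from 3.23e-10 to 1.00 for Il12a and from 4.75e-11 to 1.00 for Il12b. The edgeR quasi-likelihood count was 0, with 88 genes at an unadjusted p under 0.05, 0 with the block and with limma, and 2 with DESeq2, again Il12a and Il12b. Of the 14 IL-12 family genes 2 were higher adjusted over the list alone, over 18 libraries, with the block and within replicates 2 and 3, and 0 members of the other lists passed in these fits. Values were lower in OVAoIL12 for 19 of 19 MHC class I genes in replicate 1 and 17 of 19 in replicates 2 and 3, for 21 of 24 interferon-gamma genes in both, and for 14 and 16 of 18 NF-kB-driven genes. The cell cycle went opposite ways, lower in 25 of 25 and higher in 24 of 25.

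OVApIL12l against OVA gave Il12a at 7.80 ± 0.20 and Il12b at 7.84 ± 0.17 within replicates 2 and 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.34e-10 and 8.00e-11), also the 2 genes called. In replicate 1 they were 3.15 and 2.44, and over 18 libraries 7.30 ± 1.76 and 7.34 ± 1.91. Over the 14 alternative fits the adjusted p ran from 4.34e-10 to 1.00 for Il12a and from 8.00e-11 to 1.00 for Il12b. The count over 18 libraries was 0 with edgeR's quasi-likelihood test, with 817 genes at an unadjusted p under 0.05, 0 with the block and with limma, and 2 with DESeq2, Il12a and Il12b. Over 18 libraries 2 of 14 IL-12 family genes were higher adjusted over the list alone and 0 members of the other lists passed. Within replicates 2 and 3 these were joined by 3 of 24 interferon-gamma genes, 2 of 18 NF-kB genes and 1 of 18 RNA sensing genes, all higher, and by 1 macrophage and 1 erythroid marker, both lower. With the block 2 IL-12 family genes were higher and 1 cholesterol gene, 1 erythroid marker and 1 apoptosis gene lower, adjusted likewise. In replicate 1 the median log2 ratio of CPM + 1 was -0.12 for the interferon-gamma list and -0.05 for the NF-kB list, against 0.31 and 0.19 in replicates 2 and 3. Values of 12 of 14 class II genes were lower in OVApIL12l in replicate 1 and of 12 in replicates 2 and 3, and of RNA sensing genes 13 and 14 of 18 were higher.

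OVAoIL12 against OVA-IL12 compared arrangements with similar amounts of IL-12 reads: within replicates 2 and 3 Il12a had a mean of 2967 against 2934 CPM, a log2 difference of -0.03 ± 0.15, and Il12b 0.21 ± 0.12. Of the NF-kB-driven list 7 of 18 were lower in OVAoIL12 there. Ccl2 had 15.0 against 38.5 CPM, a log2 difference of -1.40 ± 0.18, Il6 14.3 against 35.1 CPM (-1.34 ± 0.17) and Il1a 588 against 1157 CPM (-1.02 ± 0.15). Ifnb1 was lower by -1.53 ± 0.24, the chemokine genes Cxcl10 and Cxcl9 by -0.97 ± 0.14 and -1.26 ± 0.24, and Socs1, a suppressor of cytokine signalling, by -1.33 ± 0.23. The chemokine receptor gene Ccr2 was higher by 1.60 ± 0.19, followed by Mirt1 at 1.36 ± 0.22, Nelfe at 1.17 ± 0.24 and Dysf at 1.14 ± 0.25.

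By list within replicates 2 and 3, 7 of 18 NF-kB-driven genes, 9 of 24 interferon-gamma-induced genes and 5 of 30 type I interferon genes were lower, with 0 higher in each. In the same fit adjusted over the list alone these were 18 of 18, 24 of 24 and 21 of 30, with 17 of 19 MHC class I and 13 of 19 maturation genes lower and 10 of 20 cholesterol genes higher, and any other list had at most 7 members lower and 5 higher. Over 18 libraries 0 members of any list passed adjusted over the list alone. With the block 4 of 24 interferon-gamma genes and 1 member each of the NF-kB, IL-12 family, endocytic, basophil and plasmacytoid lists were lower, and 1 conventional dendritic cell 2 marker higher, adjusted likewise. In replicate 1 the median log2 ratio of CPM + 1 was 0.02 for the NF-kB list, 0.21 for the interferon-gamma list and 0.41 for the type I interferon list, against -0.88, -0.62 and -0.35 in replicates 2 and 3. Cell cycle values were higher in OVAoIL12 for 13 of 25 genes in replicate 1 and 24 of 25 in replicates 2 and 3, with 0 past edgeR's quasi-likelihood test adjusted over the list alone, and RNA sensing values were lower for 11 and 12 of 18. Genes that were lower included Stab1, a scavenger receptor gene, at -2.10 ± 0.33 and Serpini1 at -2.08 ± 0.42, followed by Fcrlb at -1.77 ± 0.38 and the interleukin gene Il1f6 at -1.70 ± 0.35. Marcksl1 at -0.82 ± 0.15 and Jak2 at -0.76 ± 0.15 were lower, and Itgax at 0.56 ± 0.11, Mmp8 at 0.89 ± 0.12 and Sqle, an enzyme of cholesterol synthesis, at 0.54 ± 0.11 were higher. In total 227 genes changed within replicates 2 and 3, 76 higher and 151 lower, by edgeR's quasi-likelihood test. In replicate 1, 96 of these 227 went the same way, 71 of the 151 lower and 25 of the 76 higher genes. Il12a there was higher in OVAoIL12 by 2.94 and Ifnb1 by 2.09, with Ifnb1 in OVA-IL12 under the level of 3 counts. Il1f6 was 0.61 and Ccr2 0.14 apart. The difference seen within replicates 2 and 3 did not hold in replicate 1. Il12a in replicate 1 was 0.0102 of the other replicates in OVA-IL12 and 0.0768 in OVAoIL12. With such unequal reads and 1 library per group, replicate 1 cannot decide whether the arrangements differed. Over 18 libraries 0 genes changed with edgeR's quasi-likelihood test, with 214 at an unadjusted p under 0.05, and the count was 0 with the block, with DESeq2 and with limma.

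**Figure D5:**
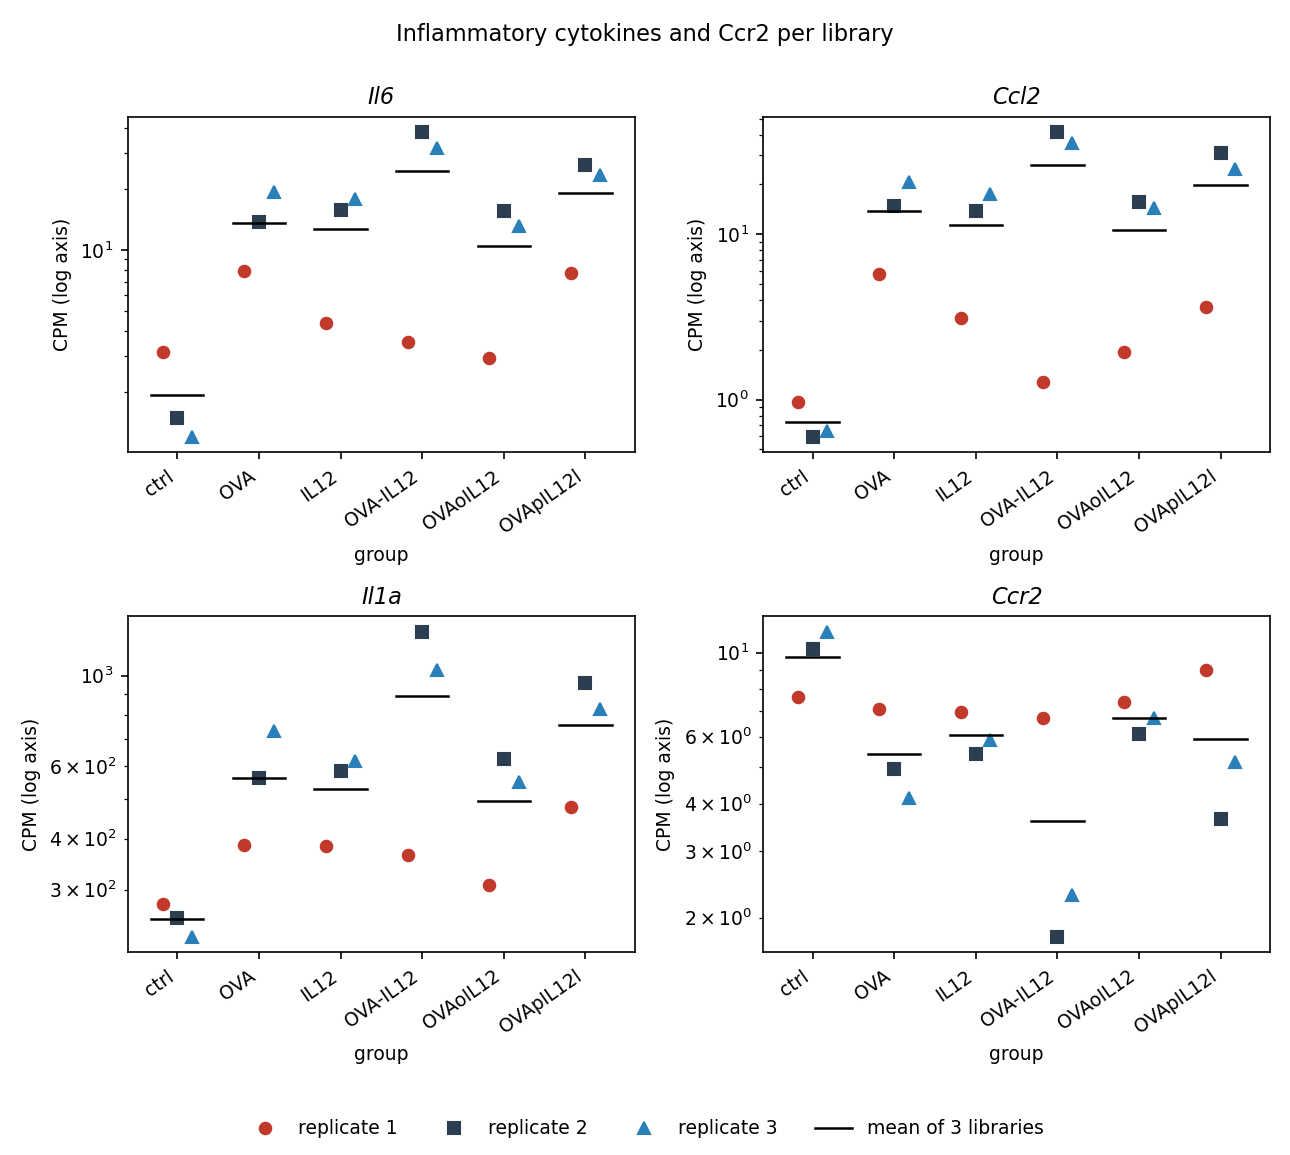
CPM of Il6, Ccl2, Il1a and Ccr2 (log axis) in each library by group, with the replicate number as shape and the mean of the 3 libraries as a line. In replicates 2 and 3, Il6, Ccl2 and Il1a are lower and Ccr2 is higher in OVAoIL12 than in OVA-IL12, for example Ccl2 at a mean of 15.0 against 38.5 CPM.

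In OVApIL12l against OVA-IL12, Il12a had a mean of 2426 against 2934 CPM within replicates 2 and 3, a log2 difference of -0.31 ± 0.15, and Il12b of -0.27 ± 0.12. Neither passed, and replicate 1 gave 1.66 for Il12a. No gene passed edgeR's quasi-likelihood test over 18 libraries, with 355 at an unadjusted p under 0.05, and the count was 0 with the block, within replicates 2 and 3, with DESeq2 and with limma. Over 18 libraries Il12a was -0.28 ± 1.34 apart. Of the lists 0 members passed over 18 libraries adjusted over the list alone. The fit of replicates 2 and 3 gave, adjusted likewise, 2 interferon-gamma genes and 1 NF-kB gene that were lower; 1 neutrophil marker was higher and 1 lower, and 1 conventional dendritic cell 2 marker was higher. The medians of the interferon-gamma and NF-kB lists were 0.34 and 0.25 in replicate 1 and -0.24 and -0.35 in replicates 2 and 3, as log2 ratios of CPM + 1. Type I interferon values were higher for 28 of 30 genes in replicate 1 and lower for 25 in replicates 2 and 3, MHC class I values higher for 11 and lower for 17 of 19, and cholesterol values lower for 12 and higher for 19 of 20. Cell cycle values were higher in 25 of 25 genes in replicate 1 and 25 of 25 in replicates 2 and 3 (medians 0.71 and 0.47), mitochondrial transcripts in 11 of 13 in both, and glycolysis and hypoxia values were lower in 18 of 20 in both (-0.49 and -0.20). Of the cell cycle, mitochondrial and glycolysis lists 0 members passed in the 3 fits adjusted over the list alone with edgeR's quasi-likelihood test. The block called 1 erythroid marker lower and 0 other members adjusted likewise.

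In OVApIL12l against OVAoIL12, Il12a was -0.28 ± 0.15 and Il12b -0.49 ± 0.12 within replicates 2 and 3, with -1.27 and -1.42 in replicate 1, and neither passed. The count was 0 over 18 libraries with edgeR's quasi-likelihood test, with 524 genes at an unadjusted p under 0.05, and 0 with the block, within replicates 2 and 3 and with limma. Over 18 libraries 0 list members passed adjusted over the list alone, and in the fit of replicates 2 and 3, 8 of 24 interferon-gamma, 5 of 30 type I interferon and 4 of 18 NF-kB genes were higher, with at most 1 member higher and 1 lower in any other list. With the block 2 class II genes, 2 macrophage markers and 1 member each of the cholesterol, erythroid and apoptosis lists were lower, adjusted likewise. In replicate 1 the medians of these 3 lists were 0.10, -0.07 and 0.27 as log2 ratios of CPM + 1, against 0.37, 0.23 and 0.44 in replicates 2 and 3. RNA sensing values were higher for 14 of 18 genes in both, and cell cycle values were higher for 25 of 25 genes in replicate 1 and lower for 21 of 25 in replicates 2 and 3. DESeq2 called 2 genes, both lower in OVApIL12l: Hexa, a lysosomal hexosaminidase subunit gene, at -0.33 on the log2 scale and Borcs6 at -0.47. They fall outside the naming rule and were chosen after their values were seen.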

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

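All tests here, the interaction included, were chosen after the results were seen. The effect of mRNA differed between replicate 1 and replicates 2 and 3, tested as an interaction, in 2760 genes for IL12, 419 for OVA, 4462 for OVA-IL12, 580 for OVAoIL12 and 2203 for OVApIL12l, each against ctrl. Of the 30 type I interferon-stimulated genes, 22, 20, 27, 23 and 25 had a smaller effect in replicate 1, with median log2 differences of -1.98, -1.83, -3.14, -2.05 and -2.54 over the 30. Each effect in replicate 1 rests on 1 library per group, and the spread of the interaction comes from replicates 2 and 3 alone.

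The pattern weighed is the weaker response of replicate 1. Lower depth was argued against by totals of replicate 1 at 0.941 of those of the others, and control libraries in the place of the replicate 1 mRNA libraries by the lowest share of interferon-stimulated genes above all ctrl libraries, 0.967. Less mRNA in the cells of replicate 1 may account for it where the Il12a reads come from the mRNA, which is open: Il12a there was at most 0.0768 of the mean of replicates 2 and 3 of the same group, and nothing comparable was measured in OVA. A difference that is there without mRNA also stays open: of 1751 genes 2-fold or more apart between ctrl replicate 1 and the other ctrl libraries, a share of 0.638 went the same way in all 5 mRNA groups, but these may share a replicate 1 shift of their own, and a shift also present in ctrl cancels in the ratio to ctrl replicate 1, so the share neither supports nor excludes it. The labels name no batch, and a biological difference between cultures was not tested.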

How the results depend on the processing

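The fit to replicates 2 and 3 and the split counts were chosen after the data were seen. Counts are given in the order IL12, OVA, OVA-IL12, OVAoIL12 and OVApIL12l against ctrl, where 45, 29, 457, 5 and 1053 genes changed. With the replicate block they were 1811, 1577, 3111, 1373 and 3889, and all genes called without it remained. For IL12 the same-numbered libraries were not paired, with a correlation of -0.0468 in pair 3, and over all groups 12 of 18 libraries correlated best with a library of their own number. In replicates 2 and 3 alone the counts were 3606, 3877, 4997, 3560 and 4705. With DESeq2 they were 609, 577, 1325, 503 and 1829, with limma on log2(CPM + 1) 94, 66 and 24 for IL12, OVA and OVAoIL12, and without a filter 1, 2, 97, 1 and 378. At an average CPM of at least 5 IL12 had 90. At a log2 fold change of at least 1, IL12, OVA, OVA-IL12 and OVApIL12l had 27, 16, 223 and 349. With edgeR on only the groups compared the counts were 0, 1, 0, 1 and 1. RLE factors, and the settings left unnamed for a comparison, gave counts within 1.5 times. Leaving out each library gave 1 to 408, 1 to 893, 1 to 1321, 1 to 404 and 66 to 1375. Without ctrl replicate 1 the counts were 408, 893, 839, 404 and 1375, without ctrl replicate 2 they were 1, 1, 1, 1 and 66, and without ctrl replicate 3 they were 1, 1, 11, 2 and 512. Leaving out the mRNA group's own replicate 1 gave 2, 3, 1321, 135 and 878, its replicate 2 gave 1, 1, 1, 1 and 525, and its replicate 3 gave 1, 1, 1, 1 and 143. Apart from the smaller number of libraries or genes that some settings have by construction, the cause was not tested.

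The comparisons with OVA gave 2 genes each within replicates 2 and 3 and 2 each with DESeq2, OVAoIL12 against OVA-IL12 gave 227 within replicates 2 and 3, and OVApIL12l against OVAoIL12 gave 2 with DESeq2, in each case from 0 over 18 libraries with edgeR. Of 220 list tests camera called 0, against 73 with a preset correlation, 91 with the block and a preset correlation, and 120 within replicates 2 and 3 with a preset correlation. Among single named genes 0 results reversed. With the block 254 passed that had not and 234 kept their side, and within replicates 2 and 3 these were 355 and 133. DESeq2 added 120. RLE factors lost 2, limma 27 with 10 gained, no filter 83, only the groups compared 113, and leaving out a library 451 with 114 gained. The block ended no call.

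Splitting the 6 libraries of a comparison in other ways gives 10 splits, too few for a share under 0.05. The real split gave 45, 29, 457, 5 and 1053 genes and the highest other split 0, 0, 370, 0 and 0, so that, counting the real split, 1 of 10 was as large in each comparison with ctrl. The split with 370 exchanged the replicate 1 libraries of OVA-IL12 and ctrl and, like the real one, parted all 3 pairs. In all, 4 of 10 splits part all 3 pairs. In the other 6 comparisons all 10 splits gave 0. Depth limits genes near the floor of at most 0.163 CPM, where Cd40 and Ccr7 lay too low to test.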

Other observations

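The fit to replicates 2 and 3 and all tests of explanations here were chosen after the results were seen. In that fit Asns, the asparagine synthetase gene, and Trib3, both of the unfolded protein response list, rose in all 5 mRNA groups, by 2.29 to 2.88 and 2.64 to 3.20 on the log2 scale (2.88 ± 0.18 and 3.20 ± 0.23 in OVA-IL12, with SE). Their log2 ratios in replicate 1 were -0.16 to 0.70 and -0.35 to 0.96, and ctrl replicate 1 itself had 52.5 CPM of Asns against 5.34 and 7.82 in the other ctrl libraries. Hdc, of the basophil and mast cell list, encodes the enzyme that makes histamine and rose by 4.43 to 5.42 (5.42 ± 0.34 in OVA-IL12), with 1.95 to 3.11 in replicate 1. Hdc had 0.200 ± 0.0504 CPM in ctrl, near the level of 3 counts, so the size of its rise is uncertain.

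Another 5 genes, chosen after their values were seen and not tested as a group, were followed in replicates 2 and 3 of the 5 mRNA groups. The scavenger receptor gene Msr1 rose by 1.65 to 2.16 (2.16 ± 0.11 in OVA-IL12), while Cd36, of the same list, was at -0.80 to -0.60 (-0.80 ± 0.07). Ly6c2, of the list of conventional dendritic cell 2 and monocyte-derived cells, rose by 2.16 to 2.99 (2.99 ± 0.32). Trem2 and Gpnmb, of the macrophage list, were at -1.07 to -0.65 (-1.06 ± 0.09) and -0.60 to -0.34 (-0.60 ± 0.10). Log2 ratios in replicate 1 were 0.44 to 0.79 for Msr1, -0.16 to 0.36 for Cd36, -0.01 to 0.56 for Ly6c2, -0.61 to -0.04 for Trem2 and -0.07 to 0.43 for Gpnmb. Over 18 libraries Hdc passed in OVA-IL12 and OVApIL12l, and the other 7 of these genes passed in none of the 5 comparisons.

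Il12a and Il12b reads in the groups given IL12 mRNA were weighed as reads of the cells' own genes or of the mRNA. Induction by transfection as such was argued against by OVA, whose mean Il12a was 0.00659 of the lowest mean of the 4 groups. Reads of the IL12 mRNA itself and induction of the cells' own genes by the IL-12 made from it cannot be told apart. That 12 of 12 libraries lay above all ctrl and OVA libraries in both genes restates the pattern and is what either would give. The ratio of Il12a to Il12b was 1.24 to 2.56, with a median of 1.49, and of the genes for the IL-12 receptor and its signal Il12rb1 had 28 counts over 18 libraries (highest 0.228 CPM), Stat4 1 count and Il12rb2 7.33 to 20.5 CPM, which leaves little sign of the means for such induction but, near the floor, does not exclude it.

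Macrophage markers lay above conventional dendritic cell markers in 18 of 18 libraries, with list medians of 58.2 to 190 CPM against 0.321 to 2.96 CPM for conventional dendritic cells 1 and 2.29 to 11.4 CPM for conventional dendritic cells 2. Too few reads was argued against by a level of 3 counts of at most 0.163 CPM. The count of 18 libraries restates the pattern, so a macrophage-like makeup of the cultures is a hypothesis without a test of its own. In ctrl Lyz2 had 23185 ± 5945 CPM, Cd68 1064 ± 352, Csf1r 1037 ± 400 and Adgre1 881 ± 334. Against a plain reading, C1qa and C1qc had 1 count each in 18 libraries and C1qb 0, Apoe had 2.79 ± 1.00 CPM in ctrl, and of the 15 genes of the list at least Lyz2, Cd68, Itgam and Cd14 are also expressed by dendritic cells grown from marrow. The labels name no sort of the cells, and Flt3, Cadm1, Mgl2 and Cd209a had 0 counts in all 18 libraries. In ctrl the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 had means of 7.28, 6.94 and 2.23 CPM. Cd74 had 19.1 and Itgax 25.4 CPM there, while Ctss, of the class II list, had 690 CPM. The 25 cell cycle genes had a median of 69.9 CPM in ctrl, with Mki67 at 500 ± 201 CPM. What these levels say about the makeup of the cultures was not tested.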
